A study of Epinephelus coioides with 9 samples.

How the data were processed

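Polyadenylated RNA from orange-spotted grouper tissue labelled as eye, at 20 days of age, was sequenced on an Illumina HiSeq instrument per the labels. There were 3 libraries each of control fish, of infected moribund fish and of infected living fish. The 9 deposited tables held 293240 genes assembled without a genome, with Trinity identifiers and the best protein match of each. The estimated counts were made with RSEM by the authors, per the submitters' processing notes, and were deposited without normalization. The FPKM values were scaled by the authors to transcript length and to mapped fragments, per the file headers. Versions of the assembler, of RSEM and of the protein database, the read mapper and the trimming are not given in the sources used here.

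Counts summed to 14170435 to 19736343 per library, and 0.79% of all values were fractional before rounding to whole numbers. Of the assembled genes, 86849 (29.6%) had a protein match. The organism of each match was sorted into broad classes by its name. Protein names were turned into gene symbols by patterns written after the files were seen, from names alone. A protein name can be shared by paralogs or by fragments of 1 gene, so the identity of an assembled gene is uncertain. The reference table held 28384 genes without usable names and was not used here.

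Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM normalization, the filterByExpr filter, group as the only factor and all 9 libraries in the fit. This left 58738 genes. A gene was called where the Benjamini-Hochberg adjusted p was below 0.05, with no minimum fold. The comparisons were moribund with control, alive with control, and moribund with alive. The SE of a log2 fold change was taken as its size over the square root of F. Where a group had no count of a gene, the fold is a lower bound that puts 3 counts in the group, and such bounds cover counting error only.

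Before the data were examined, 31 gene lists with 954 symbols were fixed, along with the tests and the rule for naming genes. Of the symbols 782 were matched, and the assembled gene with the highest mean stood for a symbol. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM (counts scaled to library size) with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over the lists. The correlation was also estimated per list, and members were counted as risen or fallen both over all genes and adjusted over the list alone. A list of fasting and muscle wasting genes was added after the data were seen and tested in the same way, without adjustment.

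Named genes were the 8 largest rises and the 8 largest falls of each comparison among genes with a name. They had to pass the test, to have non-overlapping groups and to reach a mean of 10 CPM in the higher group, with 1 gene per name. The 3 members with the smallest adjusted p were named from each list that passed, and from the interferon, rod and Muller glia lists in any case. Any nodavirus gene was to be named, and none was found. After the data were seen the rule was repeated over fish-matched genes with a mean of at least 1 CPM in the lower group. Not every gene under the rule is given in the text.

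Alternatives were DESeq2 median-of-ratios or upper-quartile factors, the DESeq2 1.42.0 Wald test, limma with trend on log2(FPKM + 1), no filter, a filter of 1 CPM in 3 libraries, and a minimum log2 fold change of 1. Others were only the 6 libraries compared, a replicate block, all assembled genes of a symbol, and each library left out in turn. A fit of fish-matched genes alone was added after the data were seen. Simulated data held 100 genes changed by a log2 fold change of 2 and another 100 changed by 1. Those changed by 2 were recovered for 62, 58 and 52 genes in the 3 comparisons, and those changed by 1 for 2, 3 and 3. A changed list of 25 genes, simulated without correlation between genes, was called in each comparison. Pairs of libraries of 1 group differed with a chi-square per degree of freedom of 8.38 to 39.5, more than counting noise alone, which does not tell separate animals from repeat preparations of 1 sample. Figures were drawn with matplotlib 3.10.9.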

Results

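Polyadenylated RNA was sequenced from orange-spotted grouper (Epinephelus coioides), a farmed marine fish, at 20 days of age, from tissue labelled as eye. The 9 libraries fell into 3 labelled groups of 3: control fish, fish infected with nervous necrosis virus and moribund, and fish infected with the virus and alive. Nervous necrosis virus is a small RNA virus that infects the brain and retina of marine fish. The question was how gene expression differed with infection and with its outcome. Estimated counts summed to between 14170435 and 19736343 per library over 293240 assembled genes, of which 58738 had enough counts to be tested. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Levels below are means ± SD over 3 libraries in CPM (counts scaled to library size), and changes are log2 fold changes ± SE.

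Counts also fell on genes of skeletal muscle, pancreas and liver and on genes matched to arthropods. Skeletal muscle genes took 22.7% ± 1.5 of the counts in the control libraries, 16.5% ± 1.03 in the moribund and 15.5% ± 2.2 in the alive libraries, against 0.104% ± 0.0646, 0.232% ± 0.0637 and 0.119% ± 0.0299 for rod photoreceptor genes (SD, n = 3). Exocrine pancreas enzymes took 0.469% ± 0.686 in control, 0.0707% ± 0.102 in moribund and 2.32% ± 0.435 in alive libraries. Liver genes took 0.837% ± 0.237, 1.13% ± 0.206 and 1.31% ± 0.0681 in the same order. A difference between groups could therefore reflect different amounts of these tissues, which was examined only for pancreas. Assembled genes whose best protein match was a crustacean took 2.14% ± 0.518 of the counts in the moribund libraries, against 0.253% ± 0.0503 in control and 0.195% ± 0.00682 in alive libraries. Genes matched to insects or other arthropods took 2.76% ± 0.655, 0.404% ± 0.0661 and 0.394% ± 0.000556 in the same order. Genes with at least 1 count numbered 144680 to 151964 in the moribund libraries and 93353 to 111292 in the others. No protein match named a virus, so the amount of virus RNA was not analysed here.

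**Figure D1:**
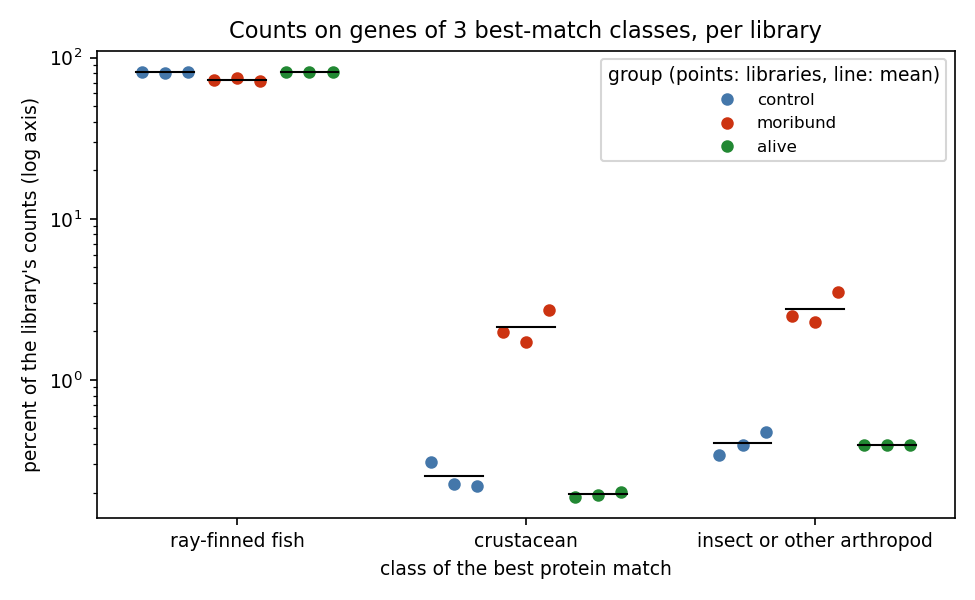
Percent of each library's counts (log axis) on genes whose best protein match was a ray-finned fish, a crustacean, or an insect or other arthropod. Points are libraries and lines are means of 3. Crustacean-matched genes took 1.73% to 2.72% in the moribund libraries and at most 0.311% in any other library.

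Libraries labelled moribund had far lower levels of antiviral genes than libraries labelled control. Groups are named as labelled here and below, and an exchange of these labels could not be told apart from a group effect. Of the 25 measured interferon-stimulated genes, 22 fell and 1 rose, with a median of -2.82 (camera adjusted p = 7.97e-15). MX1, a GTPase that blocks virus replication, was at 27.2 ± 3.67 CPM in control and 3.47 ± 0.0815 CPM in moribund libraries, a change of -2.97 ± 0.16 (adjusted p = 2.29e-05). USP18, which dampens interferon signalling, fell by 3.52 ± 0.24 (adjusted p = 3.71e-05), CMPK2, a mitochondrial nucleotide kinase, by 5.73 ± 0.39 (adjusted p = 3.81e-05), and RSAD2, the antiviral enzyme viperin, by 5.81 ± 0.41 (adjusted p = 4.25e-05). The single riser was SAMHD1, which degrades nucleotides and limits virus replication, at 0.81 ± 0.24. Adjusted over the list alone, the same numbers fell and rose. The camera call was lost with adjusted p = 0.251 with an estimated correlation.

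**Figure D2:**
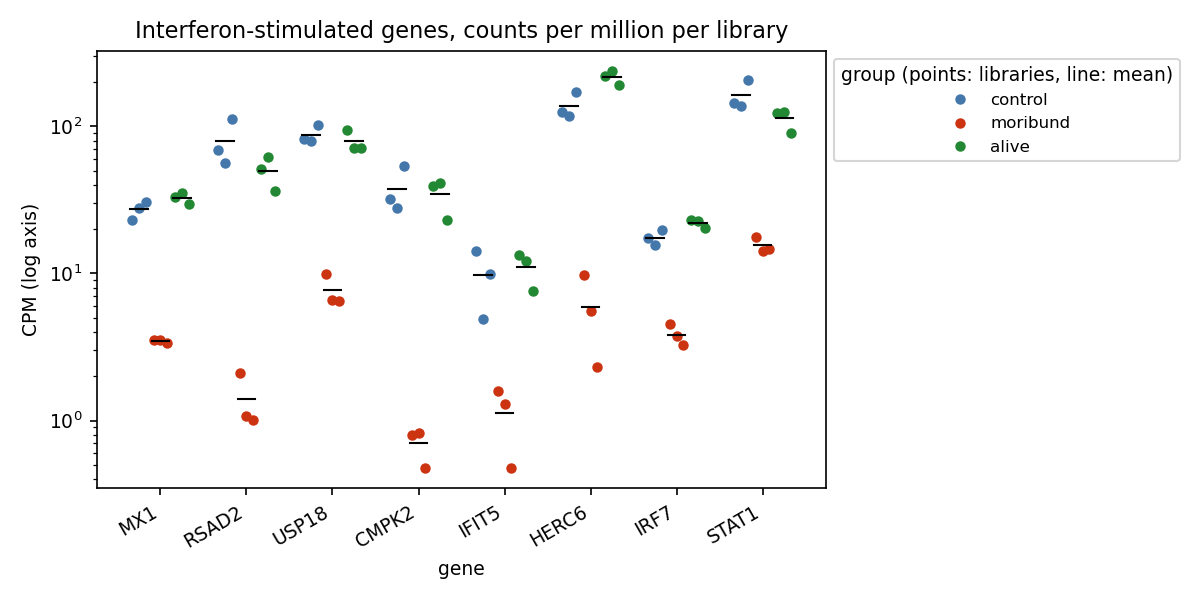
CPM (log axis) of 8 interferon-stimulated genes in each library, with lines at the mean of 3. Genes were picked for display after their values were seen. For each gene every moribund library lay below every control and alive library. MX1 averaged 3.47 CPM in moribund, 27.2 in control and 32.7 in alive libraries, and chance separates 3 libraries from 3 others, in either direction, for 10% of genes.

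Sensors and effectors of the wider immune response were lower as well. Of 24 virus sensing and signalling genes, 16 fell (17 adjusted over the list alone), with a median of -1.11. They included STING1, an adaptor of the DNA sensing pathway, at -2.51 ± 0.21, the endosomal RNA receptor TLR3 at -2.85 ± 0.32, and IRF8 at -2.53 ± 0.19. Of 25 inflammatory cytokines and mediators 14 fell (14 adjusted over the list alone), among them the chemokines CCL4 at -2.64 ± 0.23 and CXCL8 at -3.04 ± 0.35, and IL12B at -2.08 ± 0.22. Antigen presentation followed, with 9 of 14 class I genes falling and 2 rising (10 and 2 adjusted over the list alone) and 7 of 13 class II genes falling (8 adjusted over the list alone). TAPBPL, which edits peptides on class I molecules, changed by -2.61 ± 0.21, and NLRC5, the activator of class I transcription, by -3.28 ± 0.28. CTSS, a protease of class II presentation, changed by -1.95 ± 0.19. Camera adjusted p-values were 2.73e-07, 4.1e-06, 3.91e-04 and 5.46e-05 for the 4 lists in this order. Each call was lost: adjusted p = 0.251 with an estimated correlation for sensing, cytokines and class II, and adjusted p = 0.281 with an estimated correlation for class I.

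Markers of immune cells were lower in the moribund libraries too. Of 22 macrophage and microglia markers 15 fell and 1 rose (16 and 1 adjusted over the list alone), with C1QC, a complement component made by macrophages, at -2.49 ± 0.17 and lysozyme LYZ at -2.80 ± 0.23 (camera adjusted p = 3.56e-07, and adjusted p = 0.166 with an estimated correlation). Of 18 T and NK cell markers 7 fell, with IL2RG at -1.75 ± 0.18, and of 11 B cell and plasma cell markers 6 fell (7 and 7 adjusted over the list alone), with the immunoglobulin heavy chain IGHM going from 209 ± 17.2 to 16.2 ± 9.72 CPM. Of 12 neutrophil and granulocyte markers 5 fell (5 adjusted over the list alone), with the growth factor receptor CSF3R at -1.91 ± 0.18. These 3 lists had camera adjusted p-values of 3.91e-04, 0.00101 and 0.00175, all lost, with adjusted p = 0.281 with an estimated correlation for T and NK cells, 0.251 for B cells and 0.317 for neutrophils. Of 33 complement and acute phase genes 14 fell and 4 rose (17 and 5 adjusted over the list alone), including C2 at -2.56 ± 0.21, C1S at -2.48 ± 0.22 and C4B at -2.51 ± 0.33 (camera adjusted p = 0.00125, and adjusted p = 0.45 with an estimated correlation).

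Cholesterol synthesis and cell division genes moved the other way. Of 22 cholesterol synthesis genes 19 rose (21 adjusted over the list alone), with a median of 2.55. The sterol demethylase CYP51A1 went from 1.02 ± 0.187 to 75 ± 10.3 CPM (6.17 ± 0.41, adjusted p = 3.71e-05), squalene epoxidase SQLE rose by 5.63 ± 0.39, lanosterol synthase LSS by 5.75 ± 0.59, and NSDHL by 5.0 ± 0.37. Of 38 cell cycle and DNA replication genes 35 rose (36 adjusted over the list alone), with a median of 1.24. The proliferation marker MKI67 rose by 1.33 ± 0.19, UHRF1, which maintains DNA methylation, by 1.62 ± 0.19, and the replication factor CDC45 by 1.86 ± 0.26. The camera adjusted p was 8.6e-08 for cholesterol synthesis and 2.9e-06 for the cell cycle. Both calls were lost, with adjusted p = 0.251 with an estimated correlation for cholesterol synthesis and adjusted p = 0.45 with an estimated correlation for the cell cycle. Glycine amidinotransferase, the first enzyme of creatine synthesis, rose by 5.80 ± 0.67.

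Muscle and metabolism genes were among the largest falls, beside genes of other kinds. FBXO32, the ubiquitin ligase atrogin-1 of muscle wasting, went from 477 ± 144 CPM in control to 1.11 ± 0.269 CPM in moribund libraries, with 24.2 ± 12.5 CPM in alive libraries (-8.74 ± 0.53, adjusted p = 2.77e-05). Kelch-like protein 38 changed by -9.68 ± 0.91, the muscular LMNA-interacting protein by -6.37 ± 0.50, the growth factor binding protein IGFBP1 by -6.24 ± 0.91, and, by the rule repeated over fish-matched genes, the mitochondrial uncoupling protein UCP3 by -5.90 ± 0.62. Others were L-amino-acid oxidase at -6.30 ± 0.46, apolipoprotein D at -6.23 ± 1.04, a LINE-1 reverse transcriptase at -6.19 ± 0.36 and an assembled gene, 1 of several that share the protein name of IFI44, at -6.08 ± 0.64. Of 22 fasting and muscle wasting genes, a list chosen after the data were seen, 19 fell and 1 rose, with a median of -2.0 (camera p = 3.07e-10, and p = 0.0848 with an estimated correlation). A venom-like gene matched to stonustoxin subunit alpha changed by -5.91 ± 0.31. Of 27 immediate early genes 13 fell (13 adjusted over the list alone), including JUNB at -1.67 ± 0.23 and the clock gene PER1 at -4.34 ± 0.62 (camera adjusted p = 5.09e-04, and adjusted p = 0.45 with an estimated correlation). Of 32 cell death genes 14 fell and 3 rose, in the same numbers adjusted over the list alone, with GADD45B at -2.62 ± 0.29 and MCL1, which holds cell death back, at -1.39 ± 0.22, while AIFM1 rose by 1.06 ± 0.15 (camera adjusted p = 0.00518, and adjusted p = 0.317 with an estimated correlation).

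In the fit of all genes the glia and pigment epithelium lists were lower in the moribund libraries, and the rod list did not pass. Of 24 rod photoreceptor genes 6 rose (1 adjusted over the list alone), with a median of 0.73 and a camera adjusted p of 0.131. GNB1, a subunit of G proteins, rose by 0.65 ± 0.15, and the rod channel subunit CNGB1 by 1.34 ± 0.39, a call lost without control replicate 2 (adjusted p = 0.0544) or moribund replicate 1 (adjusted p = 0.0643). Of 22 Muller glia and reactive glia genes 11 fell and 5 rose, in the same numbers adjusted over the list alone. Clusterin CLU changed by -2.17 ± 0.21, HES1 by -4.60 ± 0.58 and glutamine synthetase GLUL by -3.22 ± 0.43 (camera adjusted p = 0.0241, and adjusted p = 0.29 with an estimated correlation). Of 21 genes of the retinal pigment epithelium and visual cycle 5 fell and 1 rose, in the same numbers adjusted over the list alone, with the retinol carrier RBP4 at -1.91 ± 0.16 and the pigment cell factor MITF at -1.91 ± 0.27 (camera adjusted p = 0.0215, and adjusted p = 0.45 with an estimated correlation). With all assembled genes of a symbol, neither the glia nor the pigment epithelium list passed (adjusted p = 0.0665 and 0.0642). Neither passed with only fish-matched genes in the fit (camera adjusted p = 0.114 and 0.101). Of 60 cytosolic ribosomal protein genes 4 fell and 1 rose (1 and 1 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 3.25e-04, and adjusted p = 0.628 with an estimated correlation). It did not pass with all assembled genes of a symbol (adjusted p = 0.0758). RPS2 changed by -0.60 ± 0.16, a call lost without a filter (adjusted p = 0.104) and without moribund replicate 2 (adjusted p = 0.0999) or 3 (adjusted p = 0.0602). The riser, RPL24, had its best match outside fish and was at 14.4 ± 5.42 CPM in moribund and 0.371 ± 0.507 CPM in control libraries. The remaining 14 lists did not pass, with medians of 0.11 for cone, 0.22 for inner retinal neuron, 0.22 for synapse, -0.33 for lens, 0.44 for cornea and connective tissue, -0.17 for skeletal muscle, 0.72 for red blood cell, -0.19 for protein folding, 0.40 for oxidative phosphorylation, 0.00 for glycolysis, 0.44 for mitochondrial genome, -2.84 for pancreas and gut, and -0.10 for liver genes, besides the rod list.

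In all, 15136 genes rose and 8255 fell between moribund and control libraries (edgeR quasi-likelihood test, adjusted p below 0.05), and 17 of 31 lists passed, 2 upward and 15 downward. Mixed groupings of the same 6 libraries, which keep part of the group difference, passed up to 21 lists. Arthropod-matched genes made up 40.1% of the rises, with 6067 of 6196 tested rising, and the largest rises by the naming rule were of this kind. An elongation factor 1-alpha gene was at 314 ± 157 CPM in the moribund libraries and at least 4610-fold higher than in the control libraries, which had no count of it; a crustacean vitellogenin 2 gene was at least 1200-fold higher, and myosin light chain alkali 1 at least 1120-fold higher (floor of 3 counts over the group, counting error only). Rises were 64.7% of the calls, but 49% when only fish-matched genes were fitted, a choice made after the data were seen, with 4995 rises and 5189 falls. That fit called 19 lists and shared 14 with the fit of all genes: the glia, pigment epithelium and cell death lists no longer passed (adjusted p = 0.114, 0.101 and 0.0517), while rod, synapse, red blood cell, oxidative phosphorylation and mitochondrial genome lists passed upward. With an estimated correlation these 5 had adjusted p = 0.626, 0.609, 0.228, 0.177 and 0.609.

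**Figure D3:**
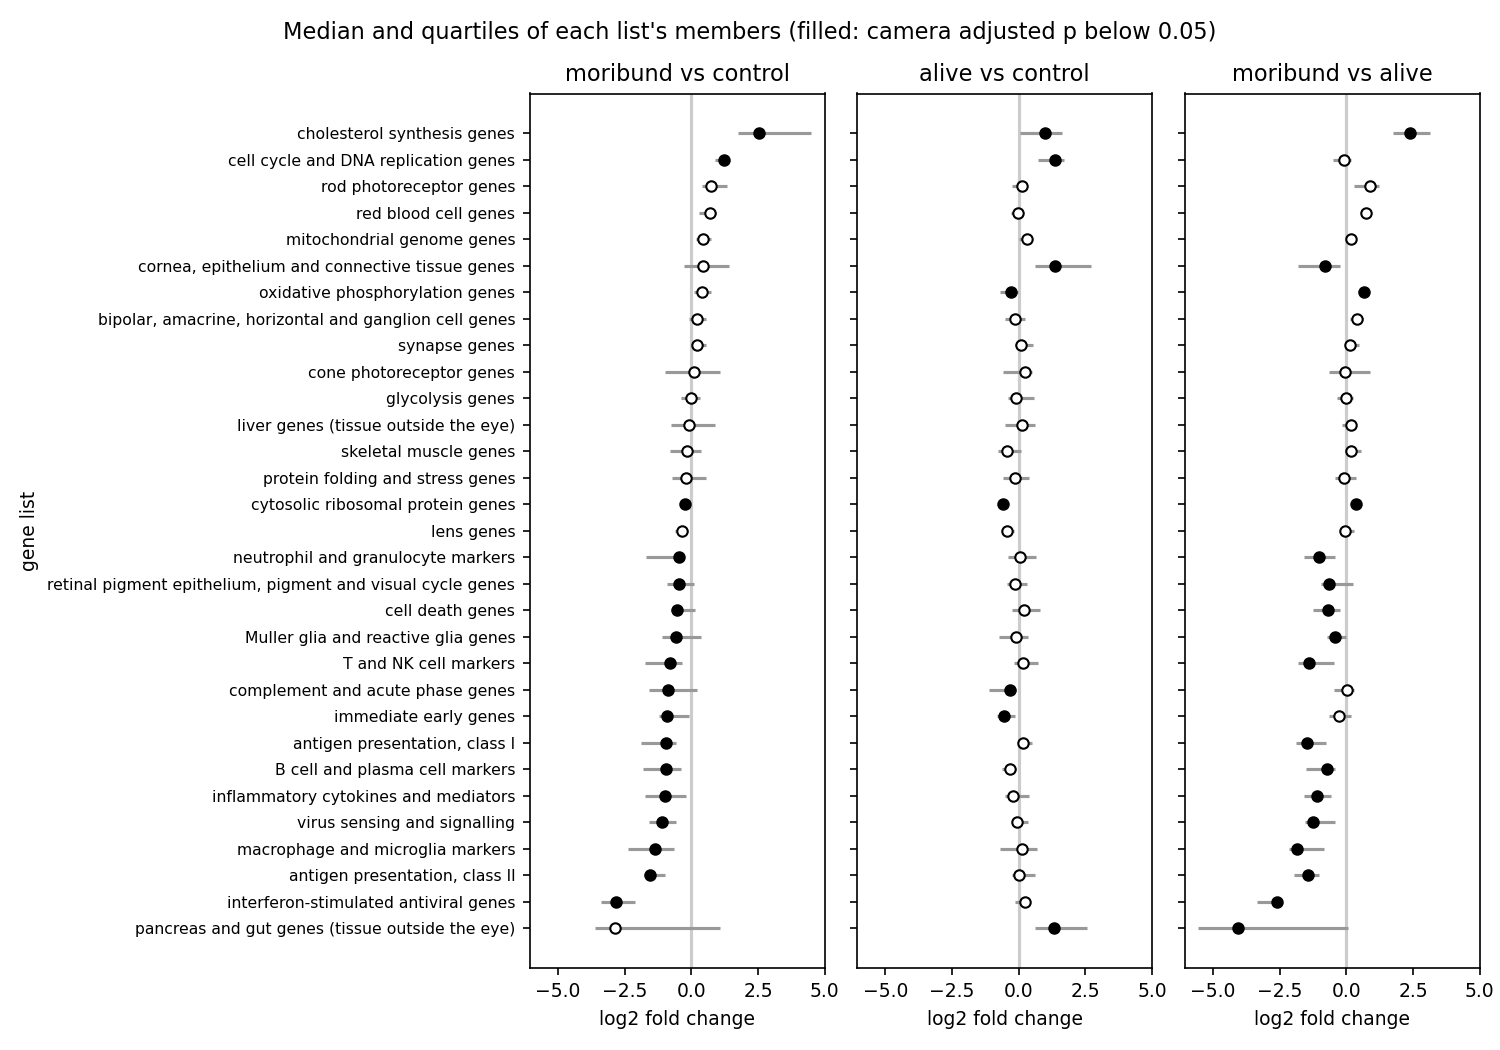
Median (points) and quartiles (lines) of the log2 fold changes of the members of each of the 31 gene lists in the 3 comparisons, with filled points where the camera adjusted p was below 0.05. The interferon-stimulated list had medians of -2.82, 0.23 and -2.61, and the cholesterol synthesis list of 2.55, 0.99 and 2.37, in the order of the panels.

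Between alive and control libraries the antiviral genes hardly differed. Of the 25 interferon-stimulated genes 2 rose and 23 did not pass (1 rose adjusted over the list alone), with a median of 0.23 and a camera adjusted p of 0.278. The assembled gene that stood for IFI44 rose by 1.35 ± 0.16 (adjusted p = 0.0014), while another with the same protein name was at 14.4 ± 5.1 CPM in control and 5.26 ± 3.51 CPM in alive libraries. MX1 was at 32.7 ± 2.93 CPM in alive and 27.2 ± 3.67 CPM in control libraries. The lists of virus sensing, cytokines, class I and class II presentation, T and NK, B, macrophage and neutrophil genes did not pass either, with medians of -0.07, -0.23, 0.15, 0.01, 0.17, -0.33, 0.13 and 0.03. Single members still differed: 2, 4, 2, 0, 0, 1, 2 and 2 rose in the same order, and 2, 4, 1, 0, 0, 2, 5 and 2 fell. IGHM was at 209 ± 17.2 CPM in control and 55.7 ± 15.4 CPM in alive libraries. Connective tissue and cell division genes were higher in the alive libraries instead.

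Of 30 cornea, epithelium and connective tissue genes 22 rose and 4 fell, in the same numbers adjusted over the list alone, with a median of 1.37 (camera adjusted p = 1.4e-07, and adjusted p = 0.93 with an estimated correlation). The collagens COL5A2 and COL6A3 rose by 2.38 ± 0.33 and 3.05 ± 0.44, and osteoglycin OGN, a matrix proteoglycan, by 3.59 ± 0.45. In moribund against control libraries 12 of the 30 genes rose too and 4 fell. COL5A2 was at 79.9 ± 35.9 CPM in control, 365 ± 26.2 in moribund and 415 ± 58.3 in alive libraries. Among single genes, mucin-2, the gel-forming mucin of the gut, went from 2.05 ± 1.32 to 216 ± 72.7 CPM (6.75 ± 0.75, adjusted p = 0.00105). Periostin, a matrix protein, rose by 4.43 ± 0.53, a second assembled gene with the protein name of COL6A3 by 5.56 ± 0.56, and the type XXII collagen chain by 4.87 ± 0.52. Of 38 cell cycle and DNA replication genes 30 rose (33 adjusted over the list alone), with TOP2A, which untangles DNA, at 2.35 ± 0.26, CDCA8 at 1.82 ± 0.21 and the checkpoint kinase BUB1 at 1.78 ± 0.20 (camera adjusted p = 2.74e-16, and adjusted p = 0.93 with an estimated correlation). Of 22 cholesterol synthesis genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), among them SQLE at 2.70 ± 0.36 and INSIG1, which restrains sterol synthesis, at 1.91 ± 0.28 (camera adjusted p = 4.83e-04, and adjusted p = 0.93 with an estimated correlation). Of 17 pancreas and gut genes 3 rose (3 adjusted over the list alone): the intestinal apolipoprotein APOA4 by 2.84 ± 0.44, the microvillus protein VIL1 by 1.01 ± 0.20 and the fatty acid carrier FABP2 by 1.84 ± 0.39 (camera adjusted p = 3.93e-04, and adjusted p = 0.93 with an estimated correlation). Between moribund and control libraries 3 genes of this list also rose and 1 fell, although the median there was -2.84.

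Genes of protein synthesis and respiration were lower in the alive libraries. Of 60 cytosolic ribosomal protein genes 28 fell (55 adjusted over the list alone), with a median of -0.58. RPL13 changed by -1.10 ± 0.20 and RPS15 by -0.92 ± 0.18 (camera adjusted p = 3.47e-14, and adjusted p = 0.93 with an estimated correlation). Of 39 oxidative phosphorylation genes 9 fell (9 adjusted over the list alone), among them the succinate dehydrogenase subunits SDHA at -1.77 ± 0.16 and SDHB at -2.67 ± 0.26 (camera adjusted p = 0.00802, and adjusted p = 0.93 with an estimated correlation). Between moribund and control libraries most calls went the other way: 16 of the 39 genes rose and 3 fell. The list had a median of 0.40 there and did not pass. Of 33 complement and acute phase genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with C5 at -1.85 ± 0.31 (camera adjusted p = 0.0182, and adjusted p = 0.93 with an estimated correlation). The list did not pass without control replicate 1 (adjusted p = 0.0813) or control replicate 2 (adjusted p = 0.078). Of 27 immediate early genes 6 fell (7 adjusted over the list alone), with IER2 at -1.14 ± 0.22 and FOS at -1.82 ± 0.36 (camera adjusted p = 0.0199, and adjusted p = 0.93 with an estimated correlation). This list did not pass without control replicate 2 (adjusted p = 0.267) or alive replicate 3 (adjusted p = 0.101).

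The largest falls from control to alive included genes that were also low in the moribund libraries. CALCOCO1, a coiled-coil coactivator, went from 601 ± 208 to 5.08 ± 2.8 CPM (-6.89 ± 0.48, adjusted p = 2.75e-04). Kyphoscoliosis peptidase, a muscle protein, was at 280 ± 2.62 CPM in control, 9.34 ± 2.75 CPM in alive and 6.66 ± 1.39 CPM in moribund libraries. Genes matched to stonustoxin subunits alpha and beta changed by -4.81 ± 0.29 and -4.49 ± 0.26, betatrophin by -6.33 ± 0.71 and kelch-like protein 38 by -4.41 ± 0.64. Rod photoreceptor genes had a median of 0.13 with 24 of 24 not passing, including GNB1 at 0.36 ± 0.15 (adjusted p = 0.116). Among glia genes, 4 rose and 6 fell, in the same numbers adjusted over the list alone. The matrix protein SPARC rose by 1.87 ± 0.33 and the list did not pass, with a median of -0.10. The lists that did not pass and have not been given above had medians of 0.23 for cone, -0.14 for inner retinal neuron, 0.07 for synapse, -0.13 for pigment epithelium, -0.43 for lens, -0.43 for skeletal muscle, -0.01 for red blood cell (0.01 with a gene absent from a whole group set at its bound), 0.18 for cell death, -0.14 for protein folding, -0.09 for glycolysis, 0.31 for mitochondrial genome and 0.11 for liver genes.

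In this comparison 5554 genes rose and 5790 fell, 17 of the rises being arthropod-matched, and 8 of 31 lists passed, 4 in each direction. Rises were 49% of the calls but 70.2% with limma on log2(FPKM + 1), where 2438 genes fell. The fish-only fit, chosen after the data were seen, moved log2 fold changes by a median of -0.14, giving 4310 rises and 4736 falls. In that fit 9 lists passed, the same 8 and, downward, skeletal muscle (camera adjusted p = 0.00245, and adjusted p = 0.912 with an estimated correlation). In the fit of all genes the counts were lower without control replicate 2 (2581 rose and 2981 fell) or 3 (3501 and 3186). They were also lower without alive replicate 1 (3889 and 3192), 2 (3340 and 3212) or 3 (2723 and 2385). Without control replicate 1, 5331 rose and 5999 fell.

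Antiviral and immune cell genes were lower in moribund than in alive libraries. The moribund libraries are the same as in the comparison with control. Of the 25 interferon-stimulated genes 24 fell (24 adjusted over the list alone), with a median of -2.61 (camera adjusted p = 2.22e-17, and adjusted p = 0.169 with an estimated correlation). MX1 changed by -3.23 ± 0.17 (adjusted p = 2.81e-05), CMPK2 by -5.60 ± 0.39 and IRF7, a driver of interferon transcription, by -2.51 ± 0.17. Of 22 macrophage and microglia markers 16 fell (17 adjusted over the list alone), with C1QB at -4.68 ± 0.47 and LYZ at -2.09 ± 0.22 (camera adjusted p = 1.11e-07, and adjusted p = 0.134 with an estimated correlation). Virus sensing genes fell in 14 of 24 cases (18 adjusted over the list alone), with STING1 at -2.83 ± 0.21 and TLR3 at -3.08 ± 0.33, and cytokine genes in 14 of 25, with CCL4 at -1.76 ± 0.23 and CCL20 at -1.50 ± 0.20. Adjusted over the list alone, 15 cytokine genes fell and 1 rose. Their camera adjusted p-values of 1.06e-07 and 1.27e-06 were lost, both with adjusted p = 0.169 with an estimated correlation.

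Antigen presentation, lymphocyte, neutrophil and cell death lists fell in the same comparison, and the complement list did not pass. Class I genes fell in 10 of 14 cases and rose in 1 (10 and 2 adjusted over the list alone), with NLRC5 at -3.74 ± 0.28 (camera adjusted p = 5.64e-05, and adjusted p = 0.179 with an estimated correlation). Class II genes fell in 10 of 13 cases (10 adjusted over the list alone), with CD40, a receptor of antigen-presenting cells, at -1.94 ± 0.23 (camera adjusted p = 1.29e-05, and adjusted p = 0.169 with an estimated correlation). T and NK cell markers fell in 9 of 18 cases (9 adjusted over the list alone), with the chemokine receptor CCR9 at -1.92 ± 0.19 and IL7R at -1.57 ± 0.23 (camera adjusted p = 2.95e-05, and adjusted p = 0.17 with an estimated correlation). B cell markers fell in 7 of 11 cases (9 adjusted over the list alone), with IGHM at -1.78 ± 0.37 (camera adjusted p = 0.00429, and adjusted p = 0.169 with an estimated correlation). Neutrophil markers fell in 7 of 12 cases (7 adjusted over the list alone), with CSF3R at -1.33 ± 0.18 (camera adjusted p = 2.6e-04, and adjusted p = 0.23 with an estimated correlation). Of 32 cell death genes 18 fell and 4 rose, in the same numbers adjusted over the list alone, with APAF1, the core of the apoptosome, at -1.83 ± 0.21 and GSDME, which opens membrane pores, at -2.10 ± 0.26 (camera adjusted p = 6.95e-05, and adjusted p = 0.17 with an estimated correlation).

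Sterol and respiration genes were higher in moribund than in alive libraries, and matrix and digestive genes lower. Of 22 cholesterol synthesis genes 18 rose and 1 fell, in the same numbers adjusted over the list alone, with a median of 2.37. FDPS, which makes the sterol precursor farnesyl diphosphate, rose by 3.74 ± 0.24 and mevalonate kinase MVK by 2.91 ± 0.20 (camera adjusted p = 3.74e-05, and adjusted p = 0.296 with an estimated correlation). Of 39 oxidative phosphorylation genes 26 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 0.66, also with the genes absent from a whole group set at their bound (camera adjusted p = 2.32e-04, and adjusted p = 0.169 with an estimated correlation). The named members COX6A1 and COX7C, subunits of cytochrome c oxidase, had no count in the alive libraries and were at least 307-fold and at least 152-fold higher in the moribund libraries, where COX6A1 was at 16.7 ± 8.79 CPM. Their best matches were vertebrates, but they were near 0 in the control libraries too, at 0.0208 ± 0.0361 and 0.118 ± 0.205 CPM. Of 60 cytosolic ribosomal protein genes 13 rose (4 adjusted over the list alone), with RPL14 at 0.82 ± 0.18 (camera adjusted p = 0.0316, and adjusted p = 0.851 with an estimated correlation). RPL14 did not pass with limma on log2(FPKM + 1) (adjusted p = 0.0749). The call of the list was also lost, with adjusted p between 0.0887 and 0.522, in every fit that left out 1 library other than moribund replicate 2 or 3. Of 30 cornea and connective tissue genes 16 fell (17 adjusted over the list alone), with POSTN, here another assembled gene than the periostin gene given against control, at -3.0 ± 0.41, COL12A1 at -2.44 ± 0.35 and decorin DCN at -3.13 ± 0.53 (camera adjusted p = 2.32e-05, and adjusted p = 0.352 with an estimated correlation).

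Digestive enzyme genes were lower in the moribund libraries and varied widely between libraries of a group. Of 17 pancreas and gut genes 5 fell (8 adjusted over the list alone), with a median of -4.06 (camera adjusted p = 0.00302, and adjusted p = 0.63 with an estimated correlation). Amylase AMY2A was at 358 ± 157 CPM in alive and 17.9 ± 19.1 CPM in moribund libraries (-4.32 ± 1.19, adjusted p = 0.0153), and the chymotrypsinogen CTRB1 at 1420 ± 161 and 28.6 ± 46.9 CPM (-5.63 ± 1.78, adjusted p = 0.029). The lipase CEL changed by -5.55 ± 1.88 (adjusted p = 0.0393). The calls of these 3 genes were lost without moribund replicate 1 (adjusted p = 0.0561, 0.066 and 0.0822) and without moribund replicate 3 (adjusted p = 0.0589, 0.0749 and 0.0901), and that of CEL without any 1 of the alive libraries (adjusted p = 0.0516 to 0.0587) or with only fish-matched genes (adjusted p = 0.0511). Among other falls, cerebellin-1, a secreted synaptic protein, changed by -7.52 ± 0.78, ependymin by -7.12 ± 1.18 and the complement C1q-like protein 3 by -6.42 ± 0.73.

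**Figure D4:**
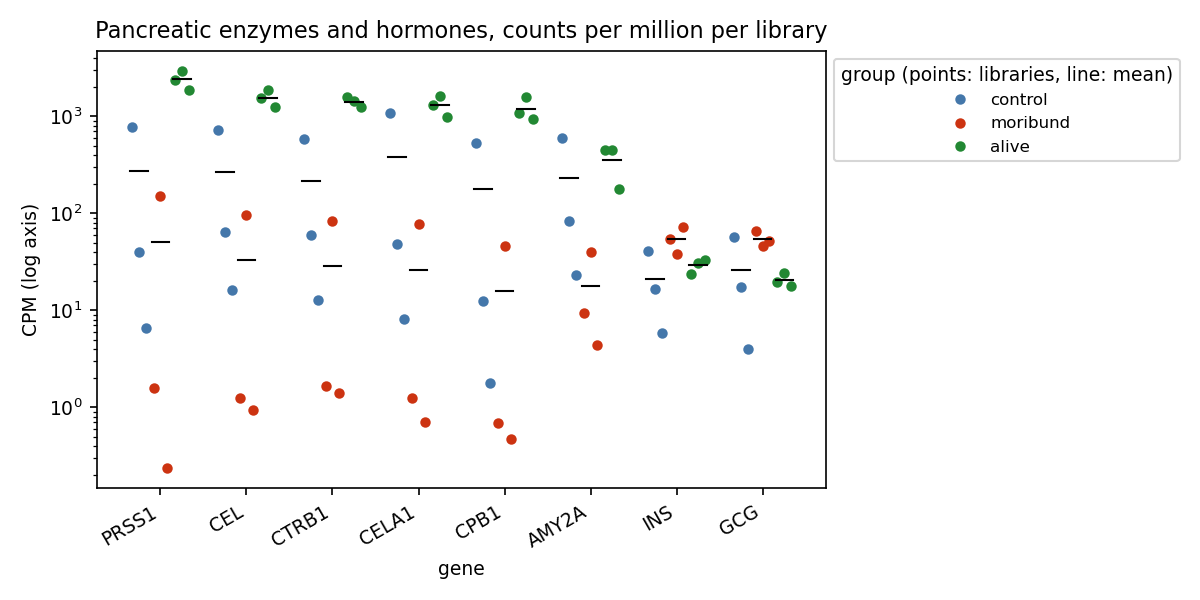
CPM (log axis) of 6 exocrine pancreas enzymes and the hormones insulin (INS) and glucagon (GCG) in each library, with lines at the mean of 3. INS, GCG, PRSS1 and CELA1 were picked for display after their values were seen. AMY2A averaged 234 CPM in control, 17.9 in moribund and 358 in alive libraries.

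In the fit of all genes the glia and pigment epithelium lists were lower in moribund than in alive libraries, and the rod list did not pass. Of 24 rod photoreceptor genes 3 rose and the list did not pass (median 0.89, camera adjusted p = 0.33). The retinol dehydrogenase RDH8 was at 111 ± 13.5 CPM in moribund and 68.8 ± 14.6 CPM in alive libraries (adjusted p = 0.0326, and not passing, with 0.0554 to 0.178, without moribund replicate 1 or 3 or alive replicate 2 or 3, nor with limma on log2(FPKM + 1), 0.0776), and none of the 24 passed adjusted over the list alone. Of 22 glia genes 7 fell and 3 rose, in the same numbers adjusted over the list alone, with CLU at -1.43 ± 0.20 and the water channel AQP4 at 1.78 ± 0.32 (camera adjusted p = 0.0272, and adjusted p = 0.241 with an estimated correlation). AQP4 was at 0.92 and did not pass with limma on log2(FPKM + 1) (adjusted p = 0.228). Of 21 pigment epithelium and visual cycle genes 5 fell and 2 rose, in the same numbers adjusted over the list alone, with STRA6, a retinol transporter, at -2.44 ± 0.51 (camera adjusted p = 0.037, and adjusted p = 0.611 with an estimated correlation). This list did not pass without moribund replicate 1 (adjusted p = 0.0559), with a filter of 1 CPM in 3 libraries (adjusted p = 0.0769) or with all assembled genes of a symbol (adjusted p = 0.127). With only fish-matched genes in the fit, neither the glia nor the pigment epithelium list passed (camera adjusted p = 0.434 and 0.461). The remaining lists did not pass, with medians of 0.04 for complement, -0.04 for cone, 0.39 for inner retinal neuron, 0.13 for synapse, -0.05 for lens, 0.19 for skeletal muscle, 0.73 for red blood cell, -0.07 for protein folding, -0.26 for immediate early, -0.07 for cell cycle, -0.01 for glycolysis, 0.19 for mitochondrial genome and 0.17 for liver genes.

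Between moribund and alive libraries 14557 genes rose and 8231 fell, and 17 of 31 lists passed, 3 upward and 14 downward. Arthropod-matched genes were 41.7% of the rises, and the largest rise by the naming rule was a crustacean myosin light chain alkali 2 gene, at least 2430-fold higher. Rises were 63.9% of the calls but 48.8% when only fish-matched genes were fitted, a choice made after the data were seen, with 4583 rises and 4803 falls and a median shift of 0.18 in log2 fold change. In that fit 21 lists passed, 15 of them shared with the fit of all genes, without the glia and pigment epithelium lists (adjusted p = 0.434 and 0.461). Rod (adjusted p = 0.00196), inner retinal neuron (1.33e-04), synapse (0.00891), skeletal muscle (0.00796), red blood cell (0.00557) and mitochondrial genome lists (0.0152) passed upward there. Their values were adjusted p = 0.593, 0.411, 0.593, 0.593, 0.147 and 0.531 with an estimated correlation, and only the macrophage and oxidative phosphorylation lists held in that fit, both with adjusted p = 0.0473 with an estimated correlation. Leaving out control replicate 1, 2 or 3, which are not part of this comparison, gave 22263, 20859 and 21874 rises. Without 1 of the alive libraries 18644 to 19823 genes rose. Without moribund replicate 1, 2 or 3 the rises numbered 14354, 19622 and 13697.

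The changes in moribund and in alive libraries, each against the control libraries, were set side by side. Across all tested genes the log2 fold changes had a Pearson correlation of -0.015 and a covariance of -0.049. Unchanged groups simulated against the same control libraries gave a correlation of 0.073 (0.055 to 0.086 over 20 simulations) and a covariance of 0.013. They were drawn around the observed mean of those libraries, so sampling error of the control libraries could not enter both changes. The simulated values are therefore no baseline for the correlation that a shared control gives. Across fish-matched genes alone, for which no unchanged groups were simulated, the correlation was 0.395 and the covariance 0.461. This gives no measure of shared change, since the control libraries are common to both. Without control replicate 3 the correlation over all genes was 0.280. Genes are not independent replicates, and the fitted changes of genes with no count in a whole group, among them 2490 arthropod-matched genes in the control libraries, depend on a prior count. In both comparisons 2430 genes rose and 2994 fell, where independent lists would share 1430 and 814, and 265 genes were called in opposite directions. Part of the excess may come from the shared control libraries, which are too few to be split.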

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

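The 10 lists given here were singled out because their camera direction against control was opposite in moribund and in alive libraries, while the direct comparison of these groups passed. They were interferon-stimulated genes (camera adjusted p = 2.22e-17), virus sensing (1.06e-07), macrophage markers (1.11e-07), class II presentation (1.29e-05) and class I presentation (5.64e-05). The others were T and NK cell markers (2.95e-05), cell death genes (6.95e-05), oxidative phosphorylation (2.32e-04), neutrophil markers (2.6e-04), and pancreas and gut genes (0.00302). Each call was lost, with adjusted p between 0.134 and 0.63 with an estimated correlation. Against control in alive libraries only oxidative phosphorylation and pancreas and gut genes passed (0.00802 and 3.93e-04), and these did not pass in moribund libraries (0.1 and 0.34), so in that fit an opposite direction was not established for any of the 10. With only fish-matched genes in the fit, oxidative phosphorylation passed upward in moribund (0.00189) and downward in alive libraries (1.25e-04), though with adjusted p = 0.177 and 0.456 with an estimated correlation. In the same fit virus sensing, class II, macrophage and neutrophil genes pointed down in alive libraries too.

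Arthropod-matched genes were higher in the moribund libraries, and the tests of this pattern were chosen after it was seen. Of the tested arthropod-matched genes 97.9% rose against control, but this restates the pattern. The low-count filter kept these genes largely through the moribund libraries, since 2490 had no count in control and 3570 none in alive libraries, so the share does not test whether the reads came from another organism. Library depth does not explain it, since after thinning to the smallest library the moribund libraries still held 9.77 times as many of these genes as the highest other group. The source of these reads stays open.

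Interferon-stimulated genes were lower in the moribund libraries than in either other group. Tests of dilution and of immune cells were chosen after this was seen. If dilution by another organism's reads were the cause, a fit of only fish-matched genes would have brought the median towards 0, but it was -2.78. That fit could hardly have come out otherwise. Fish-matched genes took 80.9% ± 0.551 of the counts in control and still 73.0% ± 1.75 in moribund libraries. A loss of share this small falls far short of the change in these genes. Fewer immune cells alone would have lowered their markers as far, but the interferon median lay -1.87 from that of 63 immune cell markers (permutation p = 1e-05, the smallest that 1e+05 permutations can give, with genes taken as independent). The interferon list had an estimated correlation of 0.538, so that p is too small. The markers pool cell types with medians from -1.37 (macrophage) to -0.46 (neutrophil), so loss of a single cell type is not excluded. Exchanged labels of the control and moribund groups could not be told apart from a group effect. Fasting and wasting genes, assumed here to be high in dying fish, had a median of -2.0 against control. That prediction was written before its result was seen, but over a list chosen after the data, so its direction may have been foreseeable. A difference between the groups as labelled stays open.

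Exocrine pancreas enzymes differed widely between groups and libraries. Varied amounts of whole pancreas, a test chosen after the result was seen, would have moved hormones and enzymes together, but of the hormones insulin and glucagon the lower change between moribund and alive libraries was 0.90, where the enzymes had a median of -5.51. Islets can lie apart from exocrine tissue in fish, so exocrine tissue alone stays open. Feeding state would have set fasting genes against enzymes throughout, a prediction written before its result was seen, over the list chosen after the data. By their medians, fasting genes and enzymes moved in opposite directions in 1 of 3 comparisons. Only in moribund against alive libraries was more than a single enzyme called, with 5 falling where 15 fasting genes fell, against that prediction. The enzymes' direction in the other comparisons is undetermined, so feeding state is left open there.

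Other splits of the 6 libraries of each comparison were tested, with predictions written before the results were seen. With 10 splits the share cannot fall under 0.1. For moribund against control the real split alone, 1 of 10, gave as many rises (15136) and as many falls (8255), and no other split called a gene with edgeR, where at most 1637 passed in 1 direction at unadjusted p. For alive against control it was also 1 of 10 in each direction (5554 and 5790, highest other 23). For moribund against alive it was 1 of 10 (14557 and 8231), with a highest other of 0 and at most 827 at unadjusted p. For gene lists, 6, 6 and 5 of 10 splits passed as many as the real 17, 8 and 17, with highest others of 21, 15 and 19, so the numbers of lists do not set the real groups apart from mixed ones. Each other split mixed libraries of both groups and kept part of the real difference, so its lists are no baseline for chance. The mixing also widens the spread within its groups, which by itself lowers the number of genes called.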

How the results depend on the processing

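Over 216 results for named genes, 3861 values under the alternatives kept direction and side of the threshold in 3767 cases, 91 lost the call, 3 gained it and 0 reversed. Without a filter 30651 genes rose in moribund against control and 30993 against alive, and the correlation of changes was 0.220. With a log2 fold change of at least 1, which by construction keeps fewer genes, 5417 fell in moribund against control, 3670 rose and 3440 fell in alive against control, and 5237 fell in moribund against alive. DESeq2 gave 23462 rises in moribund against alive, and limma on FPKM 2438 falls in alive against control; the cause was not tested. With an estimated correlation 0, 0 and 0 lists passed, where camera gave 5, 0 and 9 at unadjusted p; in the fit of fish-matched genes 2 lists of moribund against alive passed. With fish-matched genes alone, a choice made after the data were seen that by construction tests fewer genes, 4995 rose and 5189 fell in moribund against control, 4583 rose and 4803 fell in moribund against alive, and the correlation was 0.395.

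Without 1 library, rises and falls ranged over 14519 to 22406 and 5850 to 9119 in moribund against control, 2581 to 5538 and 2385 to 5999 in alive against control, and 13697 to 22263 and 5504 to 9185 in moribund against alive. The correlation ranged from -0.044 to 0.280, and lists over 17 to 20, 6 to 10 and 17 to 19; the cause was not tested. With a replicate block 14850 rose and 7774 fell, 5027 and 5001, and 14127 and 7820 in the same order, sharing 14580, 7531, 4782, 4807, 13883 and 7481 calls. Of 9 correlations between libraries of the same number 1 was over 0.1 (-0.23 to 0.28), and 2 of 18 were highest with their own number, so numbers do not pair libraries. With only 100 simulated changed genes of each size, a log2 fold change of 1 was recovered in at most 3% of them at this depth. With more changed genes the adjusted threshold is by construction less strict.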

Other observations

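Genes of fasting and muscle wasting, a list chosen after the data were seen, were high in the control libraries. The ubiquitin ligase TRIM63, which marks muscle proteins for breakdown, was at 735 ± 549 CPM in control, 108 ± 13.2 in moribund and 189 ± 84.9 in alive libraries. The autophagy receptor SQSTM1 changed by -3.66 ± 0.56 and the translation repressor EIF4EBP3 by -3.78 ± 0.29 in moribund against control (edgeR adjusted p = 7.99e-04 and 5.3e-05). KLF15, a transcription factor of the fasting response, changed by -3.90 ± 0.33. Against control the median of the 22 measured genes was -0.43 in alive libraries, with 8 falling (camera p = 0.00267, and p = 0.363 with an estimated correlation). Between moribund and alive libraries it was -1.36, with 15 falling and 1 rising (camera p = 1.83e-07, and p = 0.138 with an estimated correlation).

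Exocrine enzymes rose and fell together within groups, with a median pairwise correlation of 0.97 and a lowest of 0.89 over 10 enzymes. Insulin was at a log2 fold change of 0.90 ± 0.53 (edgeR adjusted p = 0.211) and glucagon at 1.40 ± 0.66 (adjusted p = 0.123) between moribund and alive libraries.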
